A study of Homo sapiens with 30 samples.

How the data were processed

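RPE-1 cells were transfected with 1 of 5 siRNAs and treated for 24 h with 10 µM Nutlin-3a or with its solvent DMSO, per the labels. Libraries were made from 500 ng of total RNA with a polyA kit (NEBNext Ultra II), per the labels' protocols. The 30 samples were put into 10 groups of 3 by their siRNA and treatment. The siRFXANK samples carry differently worded labels and no batch is stated, so a batch and the siRFXANK effect cannot be told apart.

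Per the submitters' processing notes, the reads were handled with bcl2fastq 2.20.0.422, Trimmomatic 0.39, FastQC 0.11.9, cutadapt 2.10, SAMtools 1.10, Picard, featureCounts 1.6.5 and DESeq2 1.20.0 on hg38. The aligner, the gene annotation and the strand setting are not given in the sources used here, so reads of antisense and overlapping genes may not be told apart. The authors deposited 12 tables, each a comparison of 2 groups, and none with values per library. In each table the authors give a signal per gene, the mean of counts divided by size factors over all libraries. The authors' log2 fold change and its standard error come next, as log2 values. Each deposited table also holds a score, the Wald statistic, and a p-value with its Benjamini-Hochberg adjusted value. The mean normalized count of a gene was identical in all 12 tables, and the log2 fold changes and squared standard errors closed around every loop of groups, so the tables are contrasts of a single fit. The total count per library is unknown. The median biological coefficient of variation recovered from the standard errors was 6.29% over 11975 genes with a mean normalized count of at least 100.

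A count test was planned had counts been given, and the authors' deposited Wald test with an adjusted p below 0.05 was used instead, since the tables hold no counts. Signs were set as knockdown over siControl and as Nutlin-3a over DMSO. The comparison of Nutlin-3a with DMSO in siRFXANK has no table of its own. Its log2 fold changes and standard errors follow from 3 deposited tables and were computed with them. Differences of Nutlin-3a effects were tested by the z of the difference of log2 fold changes, with both standard errors, two-sided, with Benjamini-Hochberg adjustment. That step was tested on simulated data for siRFX7 against siControl over 17931 genes with 200 changed. It recovered 36%, 76%, 80% and 92% of the genes changed by 0.5, 1, 2 and 3 on the log2 scale, with 7.19% false calls. Group levels and the variance of each group were derived from the same tables, and modelled standard errors had a median ratio to the deposited ones of 0.991 to 1.01.

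Gene lists (20 lists, 406 genes), comparisons, the rule for named genes and the other settings were fixed before the data were examined. The lists are direct p53 targets, G2/M genes, G1/S and replication genes, RFX7-linked genes, HLA class II, HLA class I presentation, the RFX family and cofactors, the p53 family and regulators, cholesterol synthesis, NF-kB and cytokine genes, the interferon response, the ATF4 programme, lysosome and autophagy, ribosome biogenesis, matrix and mesenchymal genes, RPE differentiation, histone genes, mitochondrial mRNAs, ribosomal proteins and markers of other cell types. For each list the members called higher and lower were counted, over all genes tested and adjusted over the list alone. The list median was placed among 10000 random lists of the same size matched on mean count in 20 bins. Named genes are the 4 targeted genes with their families, and the 8 largest rises and 8 largest falls per comparison with a mean normalized count of at least 100. They also include up to 6 members per list and comparison, 5 genes each way per difference of Nutlin-3a effects, and the 8 genes per direction of each overlap with the largest smaller fold change. Pseudogenes, readthroughs and genes without a symbol were passed over, and not every gene the rule allows is named. Where a group was under 3 counts the fold is given as a bound against that floor.

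Overlaps of knockdowns were set beside the count for independent lists and beside 100 simulations of unchanged groups against the same siControl libraries. Alternatives were an adjusted p of 0.01, a minimum log2 fold change of 1 or a fold of 1.5, a mean count of at least 100, Benjamini-Yekutieli adjustment and centring on the median. After the data were seen, comparisons without the siControl DMSO libraries, comparisons between knockdowns and overlaps with crossed treatments were added. Fits of counts, blocks by replicate number, left-out replicates, other splits of the samples and gene set tests over samples could not be run, because no values per library are given. Gene positions come from GENCODE 44. Computing used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.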

Results

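PolyA-selected RNA was sequenced from 30 cultures of RPE-1, an immortalised line of human retinal pigment epithelial cells with functional p53. The samples form 10 groups with n = 3 libraries each. They combine 5 siRNA treatments, namely a control siRNA (siControl) and siRNAs against RFX7, ANKRA2, RFXANK and TP53, with DMSO or with Nutlin-3a. Nutlin-3a releases p53 from its inhibitor MDM2, so its effect reads out p53 activity. RFX7 is a DNA-binding protein of the regulatory factor X family. ANKRA2 and RFXANK are related ankyrin-repeat proteins that bind RFX proteins, and RFXANK is a subunit of the complex with RFX5 and RFXAP that drives HLA genes. The deposited tables hold group comparisons and no values per library, so the depth of each sample is unknown. All log2 fold changes are given ± the standard error in the authors' deposited tables, and "rose", "fell" and "changed" refer to an adjusted p below 0.05 in those tables. The labels do not say whether the 3 replicates of a group were separate experiments, so the p-values measure only the spread between these libraries, which may be technical.

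The targeted genes were examined in every knockdown, since they check the labels. In the authors' deposited tables RFX7 mRNA (chromosome 15, 56087280 to 56245082, GRCh38) fell with siRFX7 by 1.55 ± 0.13 on the log2 scale in DMSO and by 2.24 ± 0.13 under Nutlin-3a. ANKRA2 mRNA (chromosome 5, 73552190 to 73565667) fell with siANKRA2 by 1.48 ± 0.12 and 1.34 ± 0.10. RFXANK mRNA (chromosome 19, 19192229 to 19201869) fell with siRFXANK by 2.44 ± 0.12 and 2.65 ± 0.12. TP53 mRNA (chromosome 17, 7661779 to 7687538) fell with siTP53 by 2.67 ± 0.07 and 2.61 ± 0.07. TP53 mRNA was also lower in the other 3 knockdowns, at −0.51 and −0.46 with siRFX7, −0.39 and −0.49 with siANKRA2, and −0.51 and −0.58 with siRFXANK. Under Nutlin-3a, siTP53 lowered RFX7 by 0.73 and ANKRA2 by 1.17, whereas in DMSO their log2 fold changes of 0.23 and −0.02 did not pass the test. RFX7 was also lower with siANKRA2 under Nutlin-3a, at −0.82, and higher with siRFXANK in DMSO, at 0.39. ANKRA2 was higher with siRFX7 in DMSO, at 0.33, and with siRFXANK in both treatments, at 0.45 and 0.27. RFXANK was lower in DMSO with siRFX7, at −0.31, and with siANKRA2 in both treatments, at −0.32 and −0.30. RFX5, the DNA-binding partner of RFXANK, fell with siRFX7 (−0.66 and −1.54) and with siANKRA2 (−0.53 and −0.95) and rose with siRFXANK (0.65 and 0.32). RFXAP, the remaining subunit, fell with siRFXANK in DMSO by 1.15.

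**Figure D1:**
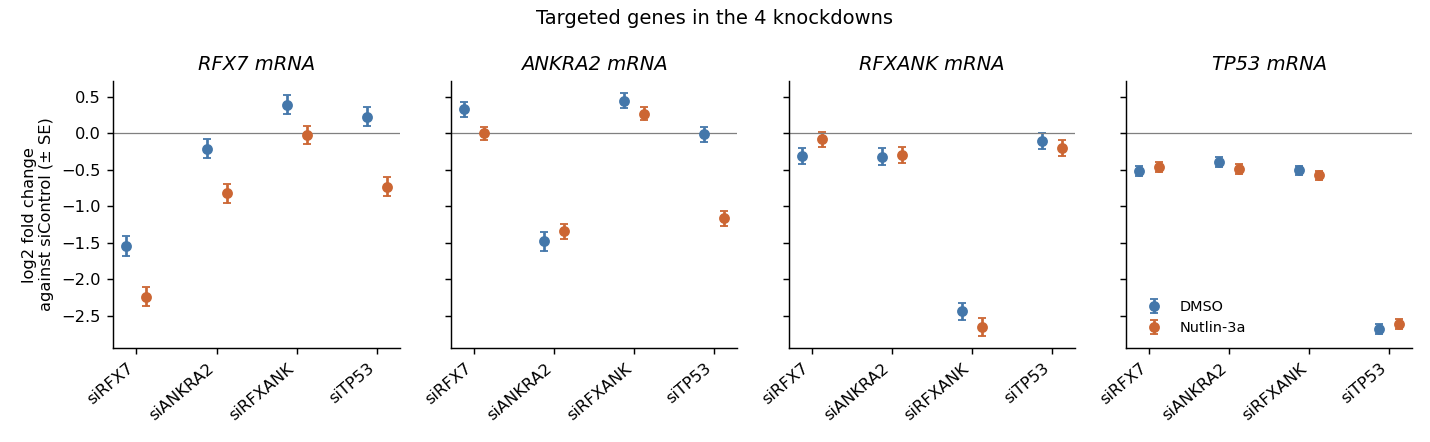
Log2 fold change against siControl (vertical axis, with standard error) of the 4 targeted mRNAs in each knockdown, in DMSO (blue) and under Nutlin-3a (orange). Each mRNA is lowest with its own siRNA, between −1.34 and −2.67.

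Every group in DMSO had genes that set it apart from the 4 others, and those of siControl behaved differently. With standard errors modelled from the deposited tables, 1825 genes were higher (1075) or lower (750) in siControl DMSO than in all 4 knockdowns in DMSO, beside 2184 for siRFX7, 2477 for siANKRA2, 2394 for siRFXANK and 743 for siTP53. The calls of the deposited tables themselves give a slightly different set of 1839 for siControl. Under Nutlin-3a the 1825 genes kept 7.08% of that median shift, while the genes that set siRFX7, siANKRA2, siRFXANK or siTP53 apart in DMSO kept between 100.3% and 107.2% of theirs. Of the genes that set a group apart under Nutlin-3a, the 678 of siControl kept 22.7% of their shift in DMSO and the 3843 of siTP53 kept 39.0%, and those of siRFX7, siANKRA2 and siRFXANK kept 79.3%, 81.1% and 85.7%. ANGPTL4, a secreted inhibitor of lipoprotein lipase on chromosome 19 (8363289 to 8374370), had the largest rise of the named genes in each knockdown in DMSO. Against siControl it rose there by 8.78 ± 0.57 with siRFX7, 7.79 ± 0.57 with siANKRA2, 5.83 ± 0.57 with siRFXANK and 4.35 ± 0.58 with siTP53. Under Nutlin-3a it kept part of that rise with siRFX7 (4.29), siANKRA2 (3.36) and siRFXANK (2.05), while −0.39 with siTP53 did not pass the test. Each DMSO comparison with siControl was therefore also made against the mean of the other 3 knockdowns in DMSO, a comparison chosen after seeing the data. Its values are given beside many of the gene groups below, and each also holds the effects of the 3 other knockdowns. For p53 targets and G2/M genes with siRFX7, siANKRA2 and siRFXANK, single knockdowns are compared below, since siTP53 can move these lists by itself. That is not shown for G2/M genes, as their median with siTP53 against siControl in DMSO was 0.013. Against the mean of the 3 others, siRFX7, siANKRA2 and siRFXANK had G2/M medians of −0.46, −0.35 and −0.06. Their p53 target medians there were 0.29, 0.15 and 0.35. Of the genes called in both comparisons, 383 turned direction for siRFX7 (2685 higher and 2830 lower in both), 580 for siANKRA2 (2489 and 2721), 387 for siRFXANK (2874 and 2654) and 1095 for siTP53 (1101 and 1163).

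**Figure D2:**
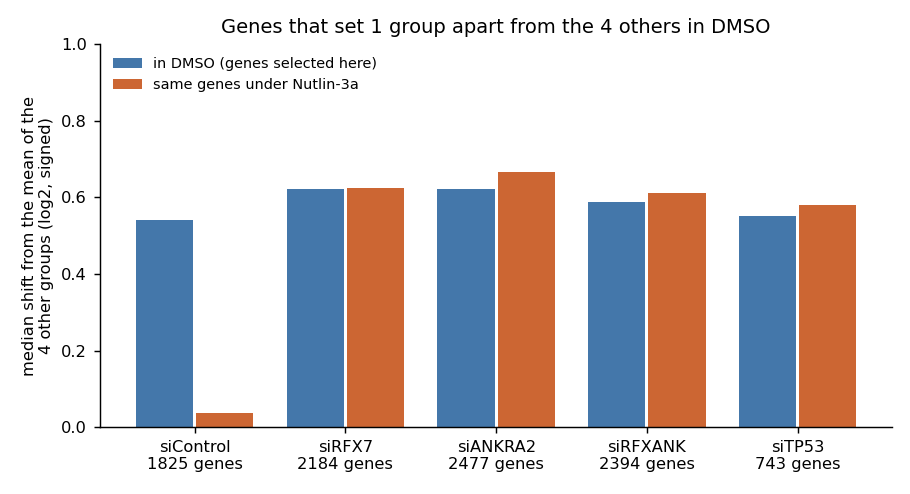
Median log2 shift, signed by its direction in DMSO, of the genes that set each group apart from the 4 other groups in DMSO (blue), and of the same genes under Nutlin-3a (orange). The 1825 genes of siControl drop to 7.08% of their shift, and those of each knockdown stay near 100.3% or above.

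Nutlin-3a against DMSO in siControl asks what p53 activation does in these cells. The authors' deposited table shows a rise of p53 target genes and a loss of cell cycle transcripts, with 5261 genes higher and 5150 lower of 24120 tested. CDKN1A, the cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687337), rose by 3.55 ± 0.34, and MDM2 (chromosome 12, 68808177 to 68845544) by 3.99 ± 0.25. Of 41 direct p53 targets 39 rose (39 adjusted over the list alone) with a median of 1.46, among them TP53I3 (2.82 ± 0.12), TIGAR (2.01 ± 0.09), the repair gene XPC (1.73 ± 0.06) and DRAM1 (1.46 ± 0.05). SFN, with a mean normalized count of 12.4, fell by 1.84, and APAF1 at 0.21 did not pass the test. All 32 genes of G2 and mitosis fell (32 adjusted over the list alone) with a median of −4.77, including PLK1 (−4.98), CDC20 (−4.81) and TOP2A (−3.78 ± 0.09). All 28 genes of G1/S and replication fell too (28 adjusted over the list alone; median −3.85), with MCM3 at −3.96 and RRM2 at −5.32. The largest rises were those of GRIN2C (5.59 ± 0.42), ANGPTL4 (5.57 ± 0.57), the phosphatase INPP5D (5.0 ± 0.28), WDR63 (4.75 ± 0.31), MDM2, the ceramidase ACER2 (3.78 ± 0.23), CDKN1A and ANK1 (3.46 ± 0.23). That of ANGPTL4 rests on a mean normalized count of 3.3 in siControl DMSO, since the count was 156.8 in siControl under Nutlin-3a but 67.4 in siTP53 DMSO, and the −0.39 ± 0.38 with siTP53 under Nutlin-3a did not pass the test. The largest falls were those of FAM111B (−7.53 ± 0.36), DTL (−6.72 ± 0.23), MCM10 (−6.71 ± 0.31), E2F2 (−6.58 ± 0.50), CCNE2 (−6.54 ± 0.33), SKA1 (−6.31 ± 0.34), SGO1 (−6.23 ± 0.35) and HJURP (−6.19 ± 0.20).

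RFX7, ANKRA2 and RFX5 rose with Nutlin-3a in siControl by 0.88, 1.18 and 0.65, and RFX2 and RFXAP fell by 1.18 and 1.14. RFXANK at 0.21 did not pass the test. Of 30 genes linked to RFX7 in the literature 29 rose (29 adjusted over the list alone; median 1.14), with TP53INP1 (3.09), TSPYL2 (1.62 ± 0.08), CALCOCO1 (1.51), the kinase subunit PIK3R3 (1.40 ± 0.07) and the translation inhibitor PDCD4 (0.86 ± 0.05; chromosome 10, 110871795 to 110900006). CCNB1IP1 fell by 0.20. That list was recalled from the literature and may have been picked in part on these libraries, so its direction is not independent evidence. Of 18 genes of the ATF4 stress and amino acid programme 12 fell and 4 rose (12 and 4 adjusted over the list alone), led by the serine synthesis enzymes PSAT1 (−2.58 ± 0.08; chromosome 9, 78297125 to 78330093) and PHGDH (−2.56 ± 0.08). Set against the siTP53 DMSO libraries in place of those of siControl, 6 of the 18 rose, 6 fell and the median was 0.11. The list median of siTP53 against siControl in DMSO was −0.66, so an effect of siTP53 and one of the siControl libraries cannot be told apart. Of 22 ribosome biogenesis genes 17 fell and 1 rose (17 and 1 adjusted over the list alone), with NOP56 at −1.18 and NCL at −0.83, and against the siTP53 DMSO libraries 16 fell.

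In siTP53 cells Nutlin-3a changed 3 genes of 38742 tested in the authors' deposited table. NANOS1 rose by 0.49 ± 0.09, FOXD1 rose by 0.29 ± 0.06, and SCD, a fatty acid desaturase, fell by 0.39 ± 0.08. No p53 target was called by the authors' DESeq2 test (0 adjusted over the list alone), with CDKN1A at 0.68 ± 0.34, MDM2 at 0.55 ± 0.25 and BTG2 at 0.71 ± 0.30. The 41 targets still had a positive median of 0.19, which lies at the percentile 100 of random lists matched on expression. No G2/M or G1/S gene was called either (0 adjusted over each list alone), with medians of −0.18 and −0.17. RFX7-linked genes had a median of 0.11, with 0 called over all genes and 6 higher when adjusted over the list alone. Over all 38742 genes tested 1308 had an unadjusted p below 0.05, a smaller share than the 0.05 that evenly spread p-values would give.

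With each of siRFX7, siANKRA2 and siRFXANK, Nutlin-3a still raised p53 targets and lowered cell cycle genes. The authors' deposited tables call 6841 genes in siRFX7 (3600 higher, 3241 lower) and 5958 in siANKRA2 (3086 and 2872), and the table derived from the deposited ones calls 6106 in siRFXANK (3115 and 2991). Of the 41 p53 targets 39, 39 and 37 rose (39, 41 and 38 adjusted over the list alone), with medians of 1.02, 1.02 and 1.01. CDKN1A rose by 2.49, 2.15 and 2.5 and MDM2 by 3.31, 3.0 and 2.84. All 32 G2/M genes fell in each (32 adjusted over the list alone), with medians of −4.04, −4.61 and −3.58. Among the largest rises in all 3 were GRIN2C (3.32, 3.81 and 4.26), INPP5D (3.56, 3.13 and 4.50) and WDR63 (2.82, 2.76 and 2.98), together with BTG2 in siRFX7 (2.36) and siANKRA2 (2.30) and PTPRU in siRFXANK (2.5). CCL3 rose by 2.2, 2.77 and 2.55, a value to treat with care because it has near-identical copies. Among the largest falls were FAM111B (−7.35, −7.30 and −6.03), MCM10 (−6.09, −7.06 and −5.35) and ESCO2 (−5.29, −6.30 and −5.07). E2F2 was at −6.58 in siRFX7 and −6.99 in siANKRA2, and in siRFXANK it lay under a floor of 3 counts over the group, at least 125-fold lower than in DMSO. Of the 30 RFX7-linked genes 22, 27 and 26 rose (23, 28 and 26 adjusted over the list alone), with lower medians of 0.42, 0.52 and 0.54. In siRFX7 cells PIK3R3 (0.12) and REV3L (0.09) did not pass the test, RFX5 fell by 0.24 and PDCD4 rose by 0.32. RFX7 itself rose in siRFXANK, by 0.47, and its values of 0.19 and 0.27 in siRFX7 and siANKRA2 did not pass the test, while ANKRA2 rose by 0.85, 1.32 and 1.0.

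**Figure D3:**
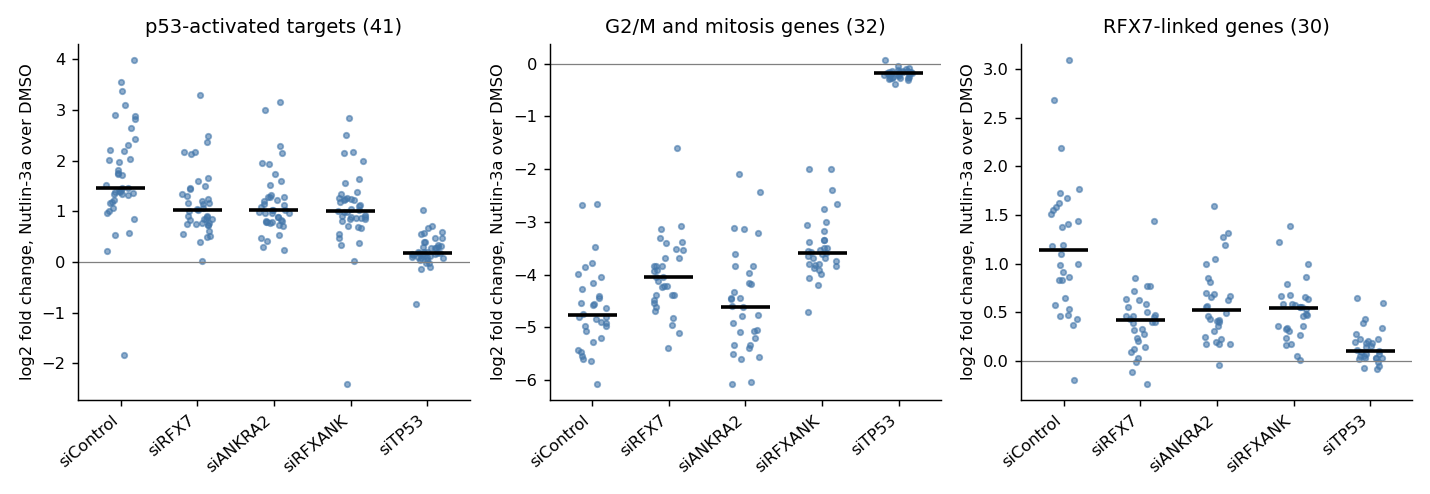
Log2 fold change of Nutlin-3a over DMSO (vertical axis) for each member (points) of 3 gene lists in cells with each siRNA, with the list median (bar). RFX7-linked genes have a median of 1.14 in siControl, 0.42 to 0.54 with siRFX7, siANKRA2 or siRFXANK, and 0.11 with siTP53.

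The difference of the Nutlin-3a effects asks which genes need the silenced factor for their response. It was tested by the z of the difference of log2 fold changes from the authors' deposited tables, with Benjamini-Hochberg adjustment. The effect differed from that in siControl for 7020 genes with siRFX7, 4792 with siANKRA2, 4364 with siRFXANK and 8202 with siTP53. The 30 RFX7-linked genes responded less with every siRNA, by a median of −0.71, −0.54, −0.51 and −1.11, with 26, 23, 26 and 28 of them called (27, 24, 27 and 28 adjusted over the list alone). The 41 p53 targets also responded less, by a median of −0.52, −0.53, −0.55 and −1.33, with 25, 32, 26 and 36 called (28, 33, 31 and 39 adjusted over the list alone). These differences contain the siControl DMSO libraries. When the Nutlin-3a effect of each knockdown was instead compared with the mean effect of the others among siRFX7, siANKRA2 and siRFXANK, 625, 429 and 374 genes differed for these 3, and 3929 for siTP53. In that comparison the p53 target median was 0.05 for siRFX7, −0.04 for siANKRA2 and −0.02 for siRFXANK. RFX7-linked genes had medians of −0.13, 0.09 and 0.01 there, with 3 lower in siRFX7, 3 higher in siANKRA2 and 2 higher in siRFXANK. With siTP53, 33 p53 targets and 19 RFX7-linked genes were lower there, and each of them was also called lower against siControl.

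siRFX7 against siControl asks which genes depend on RFX7, in unstressed cells and when p53 is active. The authors' deposited tables show that 4513 genes rose and 5078 fell in DMSO, and 4111 rose and 3623 fell under Nutlin-3a. RFX7-linked genes moved both ways in DMSO, with 9 higher and 14 lower of 30 (9 and 14 adjusted over the list alone), and fell under Nutlin-3a, with 24 lower and 1 higher (24 and 1 adjusted over the list alone; median −0.75). Under Nutlin-3a TSPYL2 fell by 2.13 ± 0.09, SESN3 by 2.17 ± 0.24, SLC43A2 by 1.94, PIK3R3 by 1.65, PIK3IP1 by 1.6, PNRC1 by 1.51, the MYC antagonist MXD4 by 1.45 and PDCD4 by 0.67. TMEM217 rose by 1.36. Against the mean of the other knockdowns in DMSO, 19 of the 30 were lower and 4 higher. p53 targets did not fall as a group with siRFX7 under Nutlin-3a, with 8 higher and 8 lower (8 and 8 adjusted over the list alone) and a median of 0.01 beside a mean of −0.01. TP53INP1 fell by 0.91, PLK2 by 0.85 and DRAM1 by 0.41, and DDB2 rose by 0.59. In DMSO 33 of the 41 rose (34 adjusted over the list alone; median 0.49), with SESN1 at 1.56, RRM2B at 1.54, CDKN1A at 1.14 and MDM2 at 0.69, while all 32 G2/M genes fell (32 adjusted over the list alone; median −1.04), with CDK1 at −1.43 and FOXM1 at −1.35. Against siANKRA2, siRFXANK and siTP53 in DMSO the p53 target medians were 0.12, 0.02 and 0.81 and the G2/M medians −0.05, −0.33 and −1.02, so most of the difference from other knockdowns is one from siTP53.

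The largest rises with siRFX7 in DMSO, after ANGPTL4, were those of LRRN1 (5.67 ± 0.34), the metalloprotease MMP24 (4.70 ± 0.13), the potassium channel KCNK3 (4.47 ± 0.32), ADAMTS14 (3.45 ± 0.16), PKIB (3.17 ± 0.12), the WNT antagonist DKK2 (3.15 ± 0.16) and MMP9 (2.92 ± 0.21). Under Nutlin-3a MMP24 (3.57 ± 0.10), PKIB (3.43 ± 0.13), LRRN1 (3.36 ± 0.19), TTC9 (3.41 ± 0.21) and the smooth muscle gene CNN1 (2.87 ± 0.11) rose most after ANGPTL4 (4.29 ± 0.38). The largest falls in DMSO included those of the cytokine IL1B (−2.34 ± 0.14), the activin antagonist FST (−2.33 ± 0.12), PSAT1 (−2.31 ± 0.08), PHGDH (−2.17 ± 0.08), MPG (−2.09 ± 0.13), PCK2 (−2.04 ± 0.09) and RPL22L1 (−1.94 ± 0.13). Under Nutlin-3a IL1B (−2.41 ± 0.14), IL6 (−2.32 ± 0.14), SCN3A (−2.13 ± 0.13), CELF2 (−2.12 ± 0.17) and the angiogenic factor VEGFA (−2.07 ± 0.10) fell most beside RFX7, SESN3 and TSPYL2. Of 17 NF-kB and cytokine genes 13 fell in DMSO and 10 under Nutlin-3a (13 and 10 adjusted over the list alone). Against the mean of the other knockdowns in DMSO 6 of the 16 genes compared were lower and 6 higher. That mean includes siRFXANK, against which 10 were higher and 4 lower with siRFX7 (median 0.64). Against siTP53 alone 9 were lower and 1 higher (median −0.34), and against siANKRA2 4 were lower and 4 higher. Of 18 ATF4 programme genes 16 fell in DMSO and 12 under Nutlin-3a (16 and 13 adjusted over the list alone; medians −1.05 and −0.47), with SHMT2 at −1.61 and −1.09 and CEBPB at −1.33 and −1.38, and 14 were lower against the other knockdowns in DMSO, with a median of −0.55.

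siANKRA2 against siControl asks the same of ANKRA2. The authors' deposited tables list 4127 genes higher and 4973 lower in DMSO, and 4152 and 4078 under Nutlin-3a. Beside ANGPTL4 (7.79 in DMSO and 3.36 under Nutlin-3a), the largest rises included those of the following genes. In DMSO and under Nutlin-3a, GDF15, a stress cytokine, rose by 6.53 ± 0.24 and 5.97 ± 0.15, the metastasis suppressor KISS1 by 6.22 ± 0.21 and 7.37 ± 0.33, and osteopontin (SPP1) by 4.41 ± 0.15 and 4.02 ± 0.13. The chaperone CRYAB (3.36 ± 0.16) and KCNQ3 (3.08 ± 0.21) followed in DMSO, and ESM1 (4.16 ± 0.15), ABCC9 (3.33 ± 0.20) and XIRP1 (3.24 ± 0.24) under Nutlin-3a. PSG5 (3.83 ± 0.16) and PSG4 (3.67 ± 0.11), which also rose in DMSO, belong to a family of near-identical genes and are uncertain. RFX7-linked genes were mostly not called in DMSO, with 11 higher and 3 lower (11 and 3 adjusted over the list alone; median 0.07), but against the other knockdowns in DMSO 5 were higher and 13 lower, with a median of −0.12. They fell under Nutlin-3a, with 23 lower and 2 higher (23 and 2 adjusted over the list alone; median −0.50). RFX5 (−0.95), PIK3R3 (−0.75), ARL15 (−0.69) and PDCD4 (−0.49) were among them, and CCNB1IP1 rose by 1.0. Of the 41 p53 targets 23 rose in DMSO (23 adjusted over the list alone; median 0.37) and 19 fell under Nutlin-3a (19 adjusted over the list alone; median −0.25), with ZMAT3 at −1.48, PLK2 at −0.86 and TNFRSF10B at −0.44. All 32 G2/M genes fell in DMSO and 24 under Nutlin-3a (32 and 24 adjusted over the list alone; medians −0.95 and −0.79), with TOP2A at −0.87 and −1.86. Against siRFXANK and siTP53 in DMSO the p53 target medians were −0.15 and 0.69 and the G2/M medians −0.23 and −0.96.

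The largest falls with siANKRA2 in DMSO were those of the antiviral gene OAS1 (−2.76 ± 0.50), CSF2 (−2.08 ± 0.13), CYP1B1 (−2.0 ± 0.20), NMU (−1.98 ± 0.21), IL6 (−1.97 ± 0.15), TSLP (−1.87 ± 0.19), NUPR1 (−1.85 ± 0.13) and KCNK2 (−1.82 ± 0.12). CYP1B1 (−2.54 ± 0.18), KCNK2 (−2.49 ± 0.12), the protease CTSS (−2.36 ± 0.15), OLFML2A (−2.35 ± 0.16), MYBL2 (−2.30 ± 0.21), IL6 (−2.25 ± 0.14), ELFN2 (−2.2 ± 0.13) and CSF2 (−2.2 ± 0.16) fell most under Nutlin-3a. Of 15 genes of HLA class I presentation 11 fell in each treatment (11 adjusted over the list alone), including HLA-F (−1.50 and −1.21), PSMB9 (−1.17 and −0.78), PSMB8 (−1.02 and −0.63), HLA-A (−0.51 and −0.42) and HLA-B (−0.40 and −0.31), whereas TAP1 at 0.09 and −0.01 did not pass the test. Against the other knockdowns in DMSO 11 of these 15 genes were lower and 1 higher, with a median of −0.43. Of 17 NF-kB and cytokine genes 12 fell in DMSO and 10 under Nutlin-3a (12 and 10 adjusted over the list alone). Against the mean of the other knockdowns in DMSO 4 of the 16 genes compared were lower and 3 higher. That mean includes siRFXANK, against which 9 were higher and 1 lower with siANKRA2 (median 0.37). Against siTP53 alone 9 were lower and 2 higher (median −0.63). HLA genes resemble each other closely, so single HLA genes are uncertain. Of 18 ATF4 programme genes 11 fell in DMSO and 13 rose under Nutlin-3a (12 and 13 adjusted over the list alone), with CHAC1 at 2.85, DDIT3 at 2.11, ATF3 at 1.94 and PSAT1 at 1.24 under Nutlin-3a. Against the other knockdowns in DMSO 12 were higher and 5 lower. Those lowered the list more against siControl, with medians of −1.055, −0.63 and −0.66 for siRFX7, siRFXANK and siTP53 beside −0.54 for siANKRA2. The comparison therefore cannot tell whether the fall comes from siANKRA2 or from the siControl libraries.

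siRFXANK against siControl asks what RFXANK does in these cells. The authors' deposited tables list 4402 genes higher and 5212 lower in DMSO, and 3925 and 3479 under Nutlin-3a. HLA class I presentation genes were lower, with 11 of 15 in DMSO and 7 under Nutlin-3a (11 and 8 adjusted over the list alone), and against the other knockdowns in DMSO 6 were lower. The peptide transporter gene TAP1 (chromosome 6, 32845209 to 32853816) fell by 1.33 ± 0.06 in both treatments, HLA-F (chromosome 6, 29722775 to 29738528) by 1.55 and 1.37, HLA-B by 0.75 and 0.76, PSMB9 by 0.70 and 0.40, and HLA-A by 0.27 and 0.23. Of the HLA class II list of 13 genes 4 were tested in DMSO and 3 under Nutlin-3a, and HLA-DMA under Nutlin-3a (−0.58 ± 0.22) was the only call. Cytokine genes were lower too, with 14 and 13 of 17 NF-kB and cytokine genes down (15 and 13 adjusted over the list alone; medians −1.44 and −1.40), and against the other knockdowns in DMSO 13 were lower, with a smaller median of −0.67. CXCL8 fell by 2.15 and 1.45, CCL2 by 1.90 and 2.02, CSF2 by 2.07 and 2.30, IL6 by 1.94 and 2.19 and the inhibitor NFKBIA by 1.44 and 1.40, and IL11 rose by 1.84 and 1.54. RFX7-linked genes rose in DMSO, 25 of 30 (25 adjusted over the list alone; median 0.51), with FAM214A at 1.51, TSPYL2 at 1.36 and PDCD4 at 0.86. Under Nutlin-3a 11 were higher and 7 lower (11 and 7 adjusted over the list alone), with a median of 0.07 and a mean of −0.04.

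**Figure D4:**
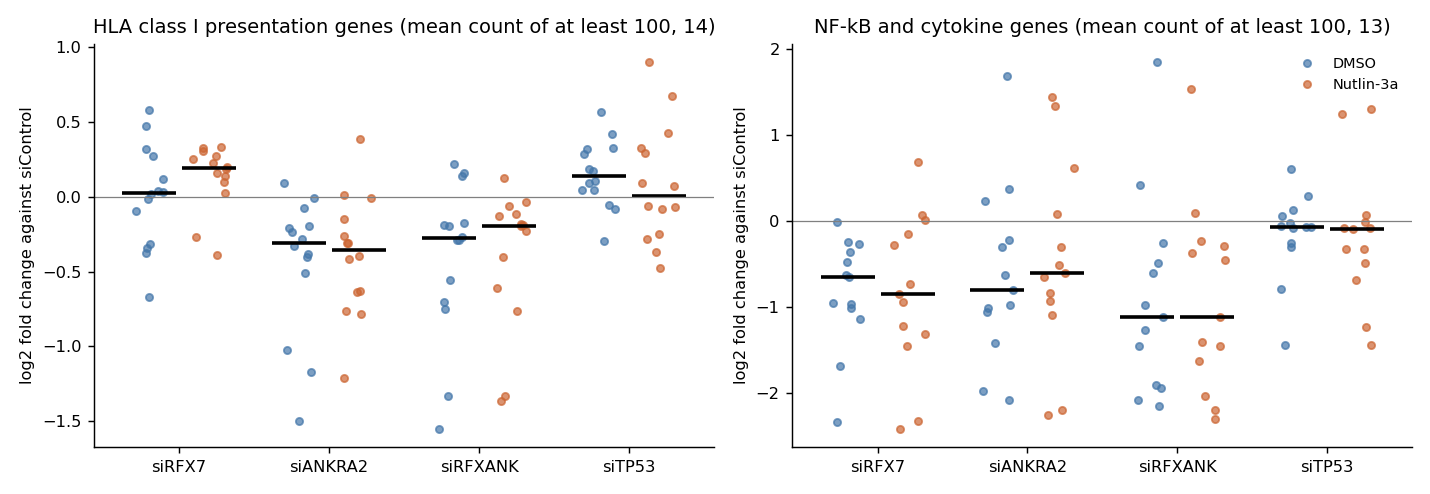
Log2 fold change against siControl (vertical axis) of the 14 class I presentation genes and the 13 NF-kB and cytokine genes with a mean normalized count of at least 100, in DMSO (blue points) and under Nutlin-3a (orange points), with medians as bars. TAP1 lies at −1.33 with siRFXANK and at 0.09 and −0.01 with siANKRA2. HLA-F in DMSO lies at −1.55 with siRFXANK and at −1.50 with siANKRA2.

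The largest rise with siRFXANK in DMSO was that of ANGPTL4 (5.83), which stayed higher under Nutlin-3a, at 2.05. XIRP1, an actin-binding protein of muscle, rose by 5.02 ± 0.18 in DMSO and 5.54 ± 0.23 under Nutlin-3a, STMN3 by 3.33 ± 0.21 and 4.73 ± 0.20, and MFAP4 by 3.75 ± 0.15 and 2.79 ± 0.14. CRYAB (3.30 ± 0.16), RGS5 (3.24 ± 0.10) and ADAMTS14 (2.80 ± 0.16) rose in DMSO, and TTC9 (3.44 ± 0.21), the BMP antagonist NOG (2.71 ± 0.08) and TNFRSF11B (2.68 ± 0.09) under Nutlin-3a. CCL3 (3.51 ± 0.24 and 3.08 ± 0.18), which has near-identical copies, and BEST1 (3.0 ± 1.24 under Nutlin-3a), whose error is large, are uncertain. Beside RFXANK and the cytokine genes CXCL8, CSF2 and IL6 given above, the largest falls in DMSO were those of TNFRSF9 (−2.71 ± 0.16), HMGB2 (−2.08 ± 0.11), the cofactor enzyme GCH1 (−1.96 ± 0.12) and MACROD1 (−1.92 ± 0.18), and under Nutlin-3a, beside RFXANK, CSF2, IL6 and E2F2, those of TNFRSF9 (−3.33 ± 0.19), PSG5 (−2.58 ± 0.18), which has near-identical relatives and is uncertain, AGAP2 (−2.40 ± 0.20) and ADGRG1 (−2.04 ± 0.12). E2F2 lay there under the floor of 3 counts over the group, at least 3.64-fold lower than in siControl. Of the 41 p53 targets 26 rose in DMSO (27 adjusted over the list alone; median 0.64), with GDF15 at 2.62, BTG2 at 1.58 and MDM2 at 1.1, while DDB2 fell by 1.06 and CDKN1A at 0.03 did not pass the test. Under Nutlin-3a 12 fell and 9 rose (16 and 9 adjusted over the list alone), with DDB2 at −1.20 and CDKN1A at −1.01. G2/M genes fell in DMSO, 29 of 32 (29 adjusted over the list alone; median −0.77), and were higher under Nutlin-3a, 19 of 32 (20 adjusted over the list alone; median 0.51), with KIF2C at 1.08 and AURKA at 1.03. Against siTP53 in DMSO the p53 target median was 0.96 and the G2/M median −0.69, while the differences from siRFX7 and siANKRA2 are given above.

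siTP53 against siControl asks which of these genes depend on p53. The authors' deposited tables hold 3018 genes that rose and 3240 that fell in DMSO, and 4659 and 4623 under Nutlin-3a. Of the 4 knockdowns, siTP53 had the most genes in DMSO that turned direction against the mean of the others, the 1095 given above. Whether this comes from the siControl libraries or from the other knockdowns was not tested. Under Nutlin-3a 38 of the 41 p53 targets fell (39 adjusted over the list alone; median −1.65) and all 32 G2/M genes (median 4.61) and 28 G1/S genes (median 3.35) rose (32 and 28 adjusted over the list alone). INPP5D (−5.08 ± 0.28), GRIN2C (−4.29 ± 0.28), WDR63 (−4.27 ± 0.28), ACER2 (−4.06 ± 0.24), CDKN1A (−3.83 ± 0.34), the patched-related gene PTCHD4 (−3.67 ± 0.32) and BTG2 (−3.62 ± 0.30) fell most. FAM111B (7.13 ± 0.36), E2F2 (6.41 ± 0.50), MCM10 (6.25 ± 0.31), SKA1 (6.17 ± 0.34), CCNE2 (6.12 ± 0.33), SGO1 (6.06 ± 0.35), DTL (5.97 ± 0.23) and ESCO2 (5.94 ± 0.28) rose most. Of the 30 RFX7-linked genes 28 fell under Nutlin-3a (28 adjusted over the list alone; median −0.79), with TP53INP1 at −3.04 and TSPYL2 at −1.11, while in DMSO 14 rose and 5 fell (14 and 5 adjusted over the list alone; median 0.19). Against the mean of the other knockdowns in DMSO 8 were higher and 7 lower with a median of 0.02, but these differed. The list was higher with siRFXANK than with siTP53 (14 higher, 1 lower; median 0.34). It was lower with siRFX7 (5 higher, 15 lower; median −0.3) and with siANKRA2 (7 higher, 8 lower; median −0.16) than with siTP53. The mean of the others therefore does not show whether siTP53 raised the list. In DMSO 21 of the 41 p53 targets fell and 2 rose (23 and 3 adjusted over the list alone; median −0.39), with CDKN1A at −0.96, BAX at −0.74 and PLK2 at −0.60, and against the other knockdowns 36 were lower and 1 higher, with a median of −0.79. G2/M genes in DMSO had a median of 0.013 beside a mean of −0.0036, with 3 higher and 3 lower (3 and 3 adjusted over the list alone), but against the other knockdowns all 32 were higher, with a median of 0.90. Other large rises in DMSO were those of NID2 (1.85 ± 0.10), SERPINB2 (1.66 ± 0.10) and PLA2G4A (1.48 ± 0.13), and the large falls beside TP53 were those of PTCHD4 (−1.81 ± 0.33), CBS (−1.79 ± 0.13), ANKRD1 (−1.70 ± 0.10), FAM96A (−1.70 ± 0.10) and GDF15 (−1.70 ± 0.45).

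Pairs of knockdowns were compared because ANKRA2 and RFXANK bind RFX proteins and because RFX7 is placed downstream of p53 in the literature. Of 20464 genes in all of the authors' deposited tables, siRFX7 and siANKRA2 moved 4833 the same way in DMSO (2036 higher, 2797 lower), against 898.6 and 1230 for independent lists, and 2613 under Nutlin-3a (1299 and 1314), against 823.4 and 718.5. Genes higher in both included IGFBP5 (2.18 and 2.99 in DMSO), SERPINB7 (2.08 and 2.52), ANOS1 (2.0 and 1.93) and, under Nutlin-3a, ABCC9 (1.75 and 3.33), and genes lower in both included PHGDH, PCK2 (−2.04 and −1.6), HMGB2 (−1.48 and −1.50) and, under Nutlin-3a, IL6, BICC1 (−1.49 and −1.52), GDF6 (−1.66 and −1.47) and TSLP (−1.41 and −1.70). siRFX7 and siRFXANK shared 5718 in DMSO (2514 higher, 3204 lower; independent lists 962.4 and 1288) and 2678 under Nutlin-3a (1469 and 1209; 783.1 and 613.3), with FAM198B (2.52 and 2.49 in DMSO), NOG (2.1 and 2.71 under Nutlin-3a) and OSBP2 (1.95 and 2.03) higher, and LOXL3 (−1.67 and −1.91 under Nutlin-3a) and MYC (−1.43 and −1.63) lower. siANKRA2 and siRFXANK, which target paralogs, shared 4981 in DMSO (2151 and 2830; 879.3 and 1260) and 2631 under Nutlin-3a (1369 and 1262; 788.8 and 689.3), with CRYAB, GDF15, XIRP1 and SPP1 higher and CSF2, IL6, TNFRSF9, HLA-F and BIRC3 (−1.43 and −1.53 in DMSO) lower. siRFX7 and siTP53 shared 3903 in DMSO (1778 and 2125; 661.6 and 802.9) and 3210 under Nutlin-3a (1564 and 1646; 927.2 and 812.7), with VAT1L (2.01 and 1.38) and GPRIN1 (1.80 and 1.78) higher and IL6, PIK3IP1 (−1.6 and −1.35), SLC43A2 (−1.94 and −1.31) and FBXO32 (−1.25 and −1.28) lower under Nutlin-3a. In DMSO these 4 pairs moved 1111, 853, 1041 and 592 genes in opposite ways, against 2103, 2227, 2105 and 1458 for independent lists. Under Nutlin-3a they moved 1656, 1386, 1617 and 1476 in opposite ways, against 1541, 1386, 1477 and 1739. Over all 20464 genes only siRFX7 with siTP53 thus had fewer opposite moves there than independent lists. With a mean normalized count of at least 100 all 4 pairs had fewer under Nutlin-3a. They moved 1495, 1251, 1502 and 1321 genes in opposite ways, against 1725, 1620, 1708 and 1980 for independent lists. Over the 11975 genes with a mean normalized count of at least 100, the covariance of the log2 fold changes in DMSO was 0.126, 0.176, 0.135 and 0.0868 for these 4 pairs, against at most 0.00578 from shared controls, and 0.0308, 0.0452, 0.0431 and 0.0528 under Nutlin-3a, against at most 0.00613. The controls could not be split, so part of the excess may come from them. Separate controls were had by taking the first of a pair in DMSO and the second under Nutlin-3a, and then the reverse. siRFX7 and siANKRA2 then moved 2226 and 2178 genes the same way, against 1910 and 1696 for independent lists, but 2701 and 2302 in opposite ways. For siRFX7 and siRFXANK 2770 and 2416 moved the same way (independent lists 1719 and 1796) and 1861 and 2310 in opposite ways, and for siANKRA2 and siRFXANK 2727 and 2339 (1626 and 1916) and 1719 and 2695. siRFX7 in DMSO and siTP53 under Nutlin-3a were mostly opposed, with 1472 genes moved the same way (2156) and 4448 in opposite ways, and the reverse pairing gave 1647 (1176) and 1470. More genes in opposite ways than in the same way were thus found in both pairings of siRFX7 with siANKRA2 and in 1 pairing each of siANKRA2 with siRFXANK and of siRFX7 with siTP53, so these comparisons do not show that the sharing is free of the controls.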

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

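The tests of the differences of Nutlin-3a effects and the tests of the control siRNA and of the siControl state for the genes shared by all 4 knockdowns were planned, and the covariance test, the tests of the cell cycle pattern, of the antigen presentation pattern and those without the siControl DMSO libraries or between knockdowns were chosen only after those results were seen. What drew attention to each gene here is that its Nutlin-3a effect differed between a knockdown and siControl, by the z test of the difference with Benjamini-Hochberg adjustment. That difference passed the test for 7020 genes with siRFX7, 4792 with siANKRA2, 4364 with siRFXANK and 8202 with siTP53. With siRFX7 the largest differences upward were those of HAUS8 (2.54), TMEM200B (2.48), ZNF367 (2.42), TEDC1 (2.15) and IMPA2 (2.04), and downward ANGPTL4 (−4.49), LRRN1 (−2.31), GRIN2C (−2.27), PCDHGC5 (−2.26) and ANOS1 (−2.12). With siANKRA2 they were those of ESM1 (2.58), CDC6 (2.47), PSAT1 (2.41), TMEM200B (2.21) and CCNE2 (2.1), and ANGPTL4 (−4.43), WDR63 (−1.99), MIR34AHG (−1.90), INPP5D (−1.87) and GRIN2C (−1.78). With siRFXANK they were those of ZNF367 (2.74), PSAT1 (2.42), PHGDH (2.18), CENPA (2.16) and CDC25C (2.15), and ANGPTL4 (−3.78), KCNK3 (−1.93), MIR34AHG (−1.80), PCDHGC5 (−1.79) and WDR63 (−1.77). With siTP53 FAM111B (7.25), MCM10 (6.51), DTL (6.46), CCNE2 (6.43) and E2F2 (6.32) led upward, and WDR63 (−4.84), ANGPTL4 (−4.74), GRIN2C (−4.51), INPP5D (−4.14) and ACER2 (−3.94) downward. PCDHGC5 shares exons with its gene cluster, MIR34AHG may overlap antisense transcripts, the place of ANGPTL4 rests on a mean normalized count of 3.3 in siControl DMSO, and all 4 sets contain the siControl DMSO libraries, without which 625, 429, 374 and 3929 genes differed.

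In DMSO 1839 genes moved the same way in all 4 knockdowns (756 higher, 1083 lower), against 28.4 and 49.4 for independent lists, with KCNK3, MDGA1, CDH6 and ANOS1 among the higher and PCK2, PSAT1, PHGDH and CSF2 among the lower. Sampling error of the shared controls is argued against by the covariance of the log2 fold changes. It was at least 0.0571 over the 6 pairs of knockdowns, beside a mean squared standard error of at most 0.0114. For the set, a control siRNA difference of like size in both treatments is argued against by the ratio of 0.0705 between its shift under Nutlin-3a and in DMSO. Such a difference hidden by Nutlin-3a was not tested. Under Nutlin-3a 115 of the 1839 genes were called the same way in all 4 knockdowns, and 12 in the opposite way. Over all genes 658 moved the same way in all 4 there (314 higher, 344 lower), against 35.7 and 27.4 for independent lists. A state of the siControl DMSO libraries alone remains open, since against the siControl Nutlin-3a libraries the 1839 genes had a signed median of 0.0383. A technical or culture difference of those 3 libraries may underlie part of every comparison that uses them. Of the 1839 genes 1555 also moved the same way with Nutlin-3a in siControl, a comparison that shares these libraries.

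In DMSO, cell cycle genes were lower and p53 targets higher with siRFX7, siANKRA2 and siRFXANK. Scaling is argued against, since after centring each table on its median the weakest of the 3 G2/M medians was −0.73. A state of the siControl DMSO libraries cannot be told apart from an effect of the knockdowns, because siTP53 shares those libraries, with a G2/M median of 0.0131, but also removes p53, which can raise these genes by itself. G1/S medians against the same libraries were −1.28, −0.92 and −1.09 with these 3 knockdowns, and −0.29 with siTP53 too. Against the mean of the other knockdowns all 28 G1/S genes were higher with siTP53, with a median of 0.78. A more active p53 pathway in the siRFX7, siANKRA2 and siRFXANK cultures is a candidate explanation, since the lowest of the 3 p53 target medians was 0.37, above the range of random lists, but these medians rest on the siControl DMSO libraries. TP53 mRNA was lower in all 3. With siRFXANK most p53 targets rose, but CDKN1A did not pass the test and DDB2 fell. Silencing by itself was not tested as a source of p53 activity.

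HLA class I presentation genes were lower with siRFXANK, at list medians of −0.29 in DMSO and −0.20 under Nutlin-3a. They were lower with siANKRA2 too, at −0.28 and −0.31. For TAP1 with siRFXANK, a state of the siControl DMSO libraries is argued against by its −1.33 against the separate siControl Nutlin-3a libraries. Against the other knockdowns in DMSO, which include siANKRA2, 6 of the 15 genes were lower with siRFXANK. For siANKRA2 the same comparison gave 11 lower. Weaker inflammatory signalling stays open as a cause. With siANKRA2 TAP1 was at 0.0928 in DMSO, but its cytokine list medians of −0.97 in DMSO and −0.51 under Nutlin-3a were not close to the −1.44 and −1.40 with siRFXANK, and gene by gene siANKRA2 lay above siRFXANK by a median of 0.37 and 0.53. HLA-F was at −1.497 with siANKRA2 too. Loss of the RFX complex at class I promoters is a hypothesis that may account for the pattern, as all 6 of HLA-A, HLA-B, HLA-C, HLA-E, HLA-F and B2M fell with siRFXANK in DMSO, but siANKRA2 lowered the same 6. With siRFX7, which lowered RFX5 mRNA, the class I list median was 0.02 in DMSO and 0.19 under Nutlin-3a, so the list did not fall. A batch of the siRFXANK libraries was not tested.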

How the results depend on the processing

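Comparisons without the siControl DMSO libraries and overlaps with crossed treatments were tests chosen only after the results were seen, and the other alternatives were planned. Of 142 counts recomputed under an alternative 91 stayed within 1.5 times and 51 moved. Among the alternatives, the differences of Nutlin-3a effects were recomputed as differences of knockdown effects (4 counts and 538 values of named genes). These have the same log2 differences and standard errors by construction. They could move only through the set of genes tested, so their stability is no support. Centring (17 counts) and a mean count of at least 100 (25 counts) moved none, and centring changed the share of higher calls most for Nutlin-3a in siRFXANK, from 51.0% to 43.2%. It turned the majority of calls from lower to higher for siRFX7, siANKRA2 and siRFXANK in DMSO (47.05% to 54.01%, 45.35% to 52.97% and 45.79% to 50.21% higher) and from higher to lower for Nutlin-3a in siRFX7, siANKRA2 and siRFXANK, for siRFXANK under Nutlin-3a and for the differences of Nutlin-3a effects with siRFX7, siANKRA2 and siRFXANK, so these balances are uncertain. Of 13316 values of named genes recomputed under 7 settings 11295 kept their side of the threshold, 2020 lost their call, 1 gained it and 0 changed direction, with 1117 of the losses at a minimum log2 fold change of 1 and 30 after centring. Only centring, with 2313 of these values, could turn a direction, because the other settings leave the log2 fold changes as they are. A mean count of at least 100 was already asked of many named genes.

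A minimum log2 fold change of 1 lowered the counts, because fewer genes can pass, to 2750, 929, 945, 1005 and 0 for Nutlin-3a in siControl, siRFX7, siANKRA2, siRFXANK and siTP53. In DMSO and under Nutlin-3a it left 1867 and 1264 for siRFX7, 1553 and 1561 for siANKRA2, 1785 and 1171 for siRFXANK, and 538 and 2141 for siTP53. For the differences of Nutlin-3a effects it left 992, 604, 595 and 2260 for siRFX7, siANKRA2, siRFXANK and siTP53. A minimum fold of 1.5 left 5445, 1996, 1883, 1981 and 0 for Nutlin-3a in the same order, 4147 and 2879, 3811 and 3389, 4250 and 2752, and 1552 and 4263 for the knockdowns, and 1465 and 632, 1887 and 601, 1496 and 651, and 707 and 731 for the overlaps of siRFX7 with siANKRA2, siRFX7 with siRFXANK, siANKRA2 with siRFXANK and siRFX7 with siTP53. At an adjusted p of 0.01 the siRFXANK difference of Nutlin-3a effects fell to 2889 and Nutlin-3a in siTP53 to 1. Benjamini-Yekutieli adjustment left 0 for Nutlin-3a in siTP53, where the authors' DESeq2 test gives 1308 of 38742 genes an unadjusted p below 0.05. It left 3799 for siTP53 in DMSO. These follow from the stricter thresholds.

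Without the siControl DMSO libraries the differences of Nutlin-3a effects became 625, 429, 374 and 3929, a comparison with the other knockdowns that answers another question. Of these, 260, 123, 111 and 1969 agreed upward with the main calls, 165, 58, 40 and 1616 downward, and 42, 51, 50 and 5 were opposite. The 5 other counts stayed within 1.5 times, but genes turned direction, 383 for siRFX7, 580 for siANKRA2, 387 for siRFXANK and 1095 for siTP53 in DMSO (1101 and 1163 kept it) and 229 for Nutlin-3a in siControl. The cause was not tested. With separate controls, that is, in opposite treatments, the overlaps were 2226 and 2178 for siRFX7 with siANKRA2, 2770 and 2416 for siRFX7 with siRFXANK, 2727 and 2339 for siANKRA2 with siRFXANK, and 1472 and 1647 for siRFX7 with siTP53. Independent lists give 1910 and 1696, 1719 and 1796, 1626 and 1916, and 2156 and 1176 in the same order. In opposite ways moved 2701 and 2302, 1861 and 2310, 1719 and 2695, and 4448 and 1470 genes. Independent lists give 1912 and 1716, 1732 and 1814, 1645 and 1918, and 2157 and 1181 for these. Sharing is thus not shown to survive for either pairing of siRFX7 with siANKRA2 or for siANKRA2 under Nutlin-3a with siRFXANK. The same holds for siRFX7 in DMSO with siTP53, which were mostly opposed. It holds too for siRFX7 under Nutlin-3a with siRFXANK or siTP53 in DMSO. With a mean count of at least 100 these last pairings moved 2105 and 1485 genes the same way, against 2055 and 1417 for independent lists. The cause was not tested. Of 335 pairs of list and comparison, 183 list medians lay outside the central 95% of random lists, 188 by means, and 158 by unmatched lists, and with a mean count of at least 100 it was 181 of 306 pairs.

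No paired analysis was possible because the deposited tables hold no per-library columns. For the same reason left-out replicates, other count models, a low-count filter other than the authors', gene set tests over samples and other splits of the samples were not run. Depth per sample is unknown, so the precision of low genes rests on the deposited standard errors.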

Other observations

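The tests in this part without the siControl DMSO libraries and between knockdowns were chosen only after the results were seen. Several gene groups outside the comparisons above moved together in the authors' deposited tables. Lysosome and autophagy genes rose with Nutlin-3a, 16 of 20 in siControl (16 adjusted over the list alone; median 0.48), with GABARAPL1 at 1.08, the cargo receptor SQSTM1 at 0.90 and LAMP1 at 0.74, with 12 higher and 3 lower against the siTP53 DMSO libraries (median 0.29), and 17, 16 and 16 rose in siRFX7, siANKRA2 and siRFXANK (18, 17 and 16 adjusted over the list alone), while siTP53 under Nutlin-3a lowered 11 (11 adjusted over the list alone). In DMSO GABARAPL1 rose by 1.71 with siANKRA2, 1.33 with siRFXANK and 1.03 with siRFX7. All 13 mitochondrial mRNAs rose with Nutlin-3a in siControl (13 adjusted over the list alone; median 0.94), with MT-ND1 at 1.05, and 12 fell with siTP53 under Nutlin-3a (12 adjusted over the list alone; median −0.55). With siRFX7 12 rose in DMSO and 9 under Nutlin-3a (12 and 9 adjusted over the list alone), and with siRFXANK 7 fell under Nutlin-3a (7 adjusted over the list alone). Matrix and mesenchymal genes rose with Nutlin-3a in siControl, 14 with 1 lower (14 and 1 adjusted over the list alone; median 0.90), with ACTA2 at 2.31, FN1 at 1.44 and COL1A1 at 1.35. Under Nutlin-3a 16 fell with siTP53 (16 adjusted over the list alone; ACTA2 −2.68, SERPINE1 −1.89), 11 with siRFX7 (11 adjusted over the list alone; COL4A1 −1.52) and 10 with siANKRA2 (10 adjusted over the list alone; THBS1 −1.75, COL1A1 −1.49). Cholesterol synthesis genes fell in DMSO with siRFX7, 16 of 19 (16 adjusted over the list alone; INSIG1 −1.37 ± 0.08, FDPS −1.24), with siRFXANK, 14 (14 adjusted over the list alone; FDPS −1.32), and with siTP53, 17 (17 adjusted over the list alone; DHCR7 −0.76), but against the other knockdowns in DMSO 16 were lower with siRFX7 only, with 7 higher and 5 lower for siRFXANK (median 0.03) and 4 higher and 4 lower for siTP53 (median −0.02). With siANKRA2 10 fell in DMSO and 9 rose under Nutlin-3a (10 and 9 adjusted over the list alone), and against the other knockdowns in DMSO 16 were higher.

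Interferon response genes moved mostly down with siANKRA2, with 8 lower and 5 higher in DMSO and 10 lower and 4 higher under Nutlin-3a (10 and 5, and 10 and 4 adjusted over the list alone), led by OAS1 (−2.76 and −1.77), IFI44 (−1.38 and −1.47) and DDX60 (−1.08 and −1.18), and against the other knockdowns in DMSO 12 were lower and 3 higher, while 9 rose with siRFX7 under Nutlin-3a (9 adjusted over the list alone; median 0.48). In siControl their median was 0.06 with Nutlin-3a and their mean −0.25, with OAS3 at −1.77, and against the siTP53 DMSO libraries 7 were lower and 2 higher. MYC fell with siRFX7 (−1.13 and −1.43) and siRFXANK (−1.38 and −1.63) and rose with siANKRA2 under Nutlin-3a by 0.34, and ribosome biogenesis genes rose with siTP53 under Nutlin-3a, 16 of 22 (16 adjusted over the list alone; median 0.62). Ribosomal protein genes fell in DMSO with siTP53 (29 of 30), siRFX7 (26) and siRFXANK (25; 29, 26 and 26 adjusted over the list alone), but against the other knockdowns 24 were lower with siTP53 (0 higher), while siRFX7 had 3 higher and 7 lower (median −0.02) and siRFXANK 4 higher and 1 lower (median 0.06). With siANKRA2 8 fell and 1 rose in DMSO (7 and 1 adjusted over the list alone), but 26 were higher and 1 lower against the other knockdowns (median 0.35). Of the 17 RPE differentiation genes 10 were tested with Nutlin-3a in siControl, and 4 rose (4 adjusted over the list alone; OTX2 0.59, MITF 0.56), while MITF, the pigment cell regulator, fell with siRFX7 by 1.05 and 1.58. Histone genes, which are near-identical copies, had a median of 0.44 and a mean of −0.48 with Nutlin-3a in siControl, with 7 higher and 3 lower (7 and 4 adjusted over the list alone), and 4 higher and 3 lower against the siTP53 DMSO libraries. Markers of other cell types, with mean normalized counts of 3.81 (DES) to 66.4 (KDR), gave 4 calls in DMSO with siRFX7 and 4 with siRFXANK (4 and 4 adjusted over the list alone), among them DES (3.17 and 3.36), a muscle filament, and PTPRC (1.79 and 2.93). Among 10 p53 family members and regulators 5 rose and 2 fell with Nutlin-3a in siControl (5 and 2 adjusted over the list alone; PPM1D 1.39), and COP1 fell with siANKRA2 by 0.54 and 0.53. Of the RFX family and cofactors 3 rose and 2 fell with Nutlin-3a in siControl (3 and 2 adjusted over the list alone), and RFX3 rose with siRFXANK by 0.65 and 0.64.

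The knockdowns also differed from each other under Nutlin-3a, by an upper limit of the standard error that counts the shared control in both comparisons. RFX7-linked genes were lower with siRFX7 than with siRFXANK (22 lower, 3 higher; median −0.87) and than with siANKRA2 (16 and 5; −0.36), and lower with siANKRA2 than with siRFXANK (22 and 2; −0.52). G2/M genes were lower than with siRFXANK both with siANKRA2 (27 and 1; −1.23) and with siRFX7 (23 and 1; −0.88), so in both lists siRFXANK lay above these 2. ATF4 programme genes were lower with siRFX7 than with siANKRA2 (14 and 0; −1.15) and than with siRFXANK (13 and 3; −0.78).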
